A study of Mus musculus with 6 samples.

How the data were processed

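Gene expression was measured with an Affymetrix gene array in whole kidneys of mouse embryos at embryonic day 14.5. Per the labels, kidneys were collected from 3 litters of crosses between Foxd1 heterozygotes, and each of the 6 arrays held RNA of a pool of 2 kidney pairs from different litters. The pools are therefore separate biological samples, 3 labelled Foxd1 null and 3 labelled wild type. With 2 of only 3 litters in each pool, any pair of pools shares at least 1 litter, so the pools are not fully independent. Which litters a pool holds is not given in the sources used here, and litter was not a term of the model. Per the labels' protocols, 50 ng of RNA was amplified to cDNA with a NuGEN whole-transcript kit and labelled with biotin. The sex of the embryos was not determined, per the series' design text.

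The values used for all tests are the deposited log2 values, 1 column per pool. The program that summarised and normalized them is not given in the sources used here. That the deposited values are on a log2 scale was read from the values: across the 440 probe sets shared with the authors' own comparison table, the slope of the differences on that table's natural-log folds was 1.43, where 1 over ln 2 is 1.443. The medians of the 6 arrays lay between 6.984 and 7.057. The authors also deposited a comparison table of 488 probe sets with a signed linear fold, a p-value, the group medians in natural log units and a p-value for expression in each group. The test behind the authors' p-value and whether it was adjusted are not given in the sources used here, and the fold equals the ratio of the medians to within rounding (largest gap 0.0049 in natural log units). A column of that table headed Chromosome held decimals from 3.56 to 9.224 and was not used. No genome build was named with the values, so no coordinates are printed.

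Rows were named through the platform annotation. Of the 35556 rows, 21789 had 1 gene symbol, 1621 had several and 12146 had none in that annotation. Symbols were compared with RefSeq names of the mouse assembly GRCm38.p6, where 21698 of the 21789 were found and 0 needed an update. One row was kept per gene, the one with the highest mean over the 6 arrays among rows with 1 symbol, which gave 19938 genes, 999 of them with more than 1 row. Genes found only on rows with several symbols, such as the adult globins and Cdkn1a, were not tested. No filter on level was applied and 0 values were missing.

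The 2 genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 arrays, genotype the only term). Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 was the threshold. All adjusted p-values of genes come from this test unless another is named. All differences are the mean of the null-labelled pools minus the mean of the wild type pools in log2 units, given with the standard error (SE) of the model; levels are means ± SD over n = 3 pools. Intervals are at 95%. The number of arrays limits the precision: the median SE was 0.086, and an exact test of 3 against 3 cannot give a two-sided p under 0.1. Tables were joined and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

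Gene lists for kidney cell types, matrix, signalling and cell states, and for neighbouring tissues, blood and sex, were fixed before the data were examined. Of their 666 genes 614 were measured, and the 37 lists with at least 3 measured genes were tested with limma's camera at its preset correlation of 0.01. The p-values of lists were adjusted over the 37 lists. Camera with an estimated correlation and fry were run beside it. For each list the number of members past the threshold was also counted with p-values adjusted over the list alone. The list of small leucine-rich proteoglycans was made knowing that the study worked on decorin.

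The rule for the genes named in the text was also fixed beforehand. It took Foxd1, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members per list past the threshold with the largest differences. Where no member of a list passed, up to 2 members with the highest level were taken. Dcn, Six2, Ren1, Aldh1a2 and Sfrp1 were to be named whatever they showed, but Ren1 was not among the genes tested. The rule gave 106 genes. Genes named outside it are said to have been chosen after their values were seen.

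The test was tried on simulated data for this comparison with 19938 genes. All 100 genes changed 2-fold and 80 of 100 genes changed 1.5-fold were recovered, 0 in the wrong direction, with 9 false calls. The simulated variances were drawn from the prior that limma fitted here, with normal errors and independent pools. The simulation thus met the assumptions of the test and does not show its error rate in the real pools. With no change simulated camera called 0 of 37 lists, and a list shifted by 0.3 was called. The simulated genes were drawn independently of each other, so this does not show how camera behaves on lists of correlated genes. On the real arrays camera called 4 to 15 lists in splits that mix the labels, as given below. The alternatives tried were leaving out each pool in turn, replicate number as a block, quantile normalization, median centring, a filter on low rows, other variance models, array weights, other choices of rows, a fold threshold and a plain two-sample test per gene. A fit with Xist as a covariate and a fit on all rows with an intensity trend were chosen after seeing the data.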

Results

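Expression was measured on 6 arrays, each holding RNA of a pool of 2 pairs of E14.5 mouse kidneys, 3 pools labelled Foxd1 null and 3 labelled wild type. Foxd1 encodes a forkhead transcription factor made in the stromal progenitors of the developing kidney. The comparison asks which transcripts differ between kidneys labelled Foxd1 null and those of wild type littermates. Pearson correlations across all rows of the array between arrays of the same genotype averaged 0.989 to 0.993 per array. The arrays did not all correlate best with their own group: null-labelled pool 1 averaged 0.9906 with the wild type arrays and 0.9896 with its own group, pool 2 averaged 0.9896 and 0.9903, and pool 3 0.9863 and 0.9892.

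The Foxd1 row stood at 9.84 ± 0.18 in the pools labelled null and at 9.55 ± 0.15 in the wild type pools (n = 3 each), a difference of 0.30 (SE 0.11, adjusted p = 0.246). Its values were 10.05, 9.77 and 9.71 in null-labelled pools 1, 2 and 3, and 9.40, 9.55 and 9.69 in wild type pools 1, 2 and 3. The row was therefore not lower in any pool labelled null. This goes against the label unless the row lies outside the deleted part of the gene, in which case it checks nothing. The sources used here do not say which part the allele lacks, and the positions of the probes were not used. Every direction below is between pools as labelled.

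Decorin (Dcn), a small leucine-rich proteoglycan of collagen matrix, rose from 10.41 ± 0.10 to 11.77 ± 0.14, which is 2.57-fold (SE 0.09 in log2, n = 3 per group, adjusted p = 0.000316). Lhx1, a transcription factor of the renal vesicle, fell from 8.26 ± 0.06 to 7.08 ± 0.12 (log2 difference -1.18, SE 0.08, n = 3 per group, adjusted p = 0.000316). Aldh1a2, which makes retinoic acid in the cortical stroma, fell from 10.71 ± 0.09 to 9.94 ± 0.19 (log2 difference -0.77, SE 0.10, adjusted p = 0.00473). Six2, the marker of self-renewing nephron progenitors, had a log2 difference of -0.43 (SE 0.09, adjusted p = 0.0502) and did not pass the threshold. Six2 did pass in 9 of its 14 alternatives (adjusted p 0.0202 to 0.215 over all 14), among them the replicate block (0.0366), quantile normalization (0.0359), median centring (0.0439), and the fits without null-labelled pool 1 (0.0297) or wild type pool 2 (0.0481). Sfrp1, a Wnt antagonist of the stroma, had a log2 difference of 0.21 (SE 0.12, adjusted p = 0.496).

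In all, 479 of 19938 genes passed the threshold, 326 higher and 153 lower in the pools labelled null, and in each of the 479 the groups did not overlap. Over all genes, 3888 (19.5%) had groups without overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 2811 genes. Among the 479, 164 rose and 90 fell by at least 1.5-fold, and 43 rose and 28 fell by at least 2-fold. The counts rest on few pools and on the variance model. Without null-labelled pool 1, 2 or 3 they were 572 higher and 171 lower, 127 and 76, or 182 and 104, and without wild type pool 1, 2 or 3 they were 130 and 64, 140 and 72, or 207 and 140. A test over all rows of the array called 71 rows higher and 37 lower, of which 8 and 7 carry no single gene symbol. It kept 90 of the 479 calls. A plain two-sample test per gene called 1 and 1. Other models raised the counts, to 394 and 196 with an intensity trend and 452 and 221 with the trend and robust variance model. Array weights gave 385 and 184.

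The 12 largest rises among these genes were those of Prss35, Sulf1, Mgp, Lum, Pi15, Acta2, Fbln5, Slc26a7, Thbs2, Grin3a, Actg2 and Dcn. Prss35, a secreted serine protease family member, rose by 2.20 (SE 0.17, 4.59-fold, adjusted p = 0.000402). Sulf1, an extracellular heparan sulfate sulfatase, rose by 1.99 (SE 0.16, 3.98-fold). Mgp, matrix Gla protein, rose by 1.79 (SE 0.14, 3.45-fold). Pi15 rose by 1.53 (SE 0.13), and the elastic fibre protein Fbln5 rose by 1.45 (SE 0.14). The anion transporter Slc26a7 rose by 1.44 (SE 0.10), and the NMDA receptor subunit Grin3a rose by 1.38 (SE 0.08). Adjusted p for the 12 ranged from 0.000197 to 0.0024, and all 12 stayed past the threshold without any single pool.

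The 12 largest falls were those of Sult1d1, Cyp4a31, Keg1, Slc12a1, Dpp4, Car4, Anxa13, Kynu, Mep1a, Cltrn, Tmem52b and Spink1. The sulfotransferase Sult1d1 fell by 3.13 on the log2 scale (SE 0.41, adjusted p = 0.00464), from 8.05 ± 1.08 to 4.92 ± 0.14. Cyp4a31 fell by 2.85 (SE 0.29); its row could also bind RNA of close paralogs, so its identity is uncertain. Of the 10 of these genes in the authors' deposited table, 9 have an expressed p-value of 0.05 or more in null there (all but Dpp4), so the sizes of these falls end near background and are no exact folds. Cltrn, Mep1a, Slc12a1 and Cyp4a31 have one of 0.05 or more in wild type too (0.155, 0.0819, 0.137 and 0.178), so the order of the largest falls is uncertain. In wild type pool 3 Sult1d1 stood at 6.81 against 8.84 and 8.50 in pools 1 and 2, and without that pool its log2 difference was -3.75. Dpp4, a brush border peptidase, fell by 1.88 (SE 0.21), and the membrane carbonic anhydrase Car4 fell by 1.77 (SE 0.17). Anxa13 fell by 1.77 (SE 0.13) and Kynu, an enzyme of tryptophan breakdown, fell by 1.74 (SE 0.10). The brush border protease Mep1a fell by 1.71 (SE 0.25), Cltrn by 1.69 (SE 0.22) and Spink1 by 1.67 (SE 0.15). All 12 stayed past the threshold without any single pool, while Sult1d1, Slc12a1 and Mep1a did not pass with the trend and robust variance model. Their adjusted p there was 0.112, 0.0694 and 0.081, the highest over their alternatives.

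**Figure D1:**
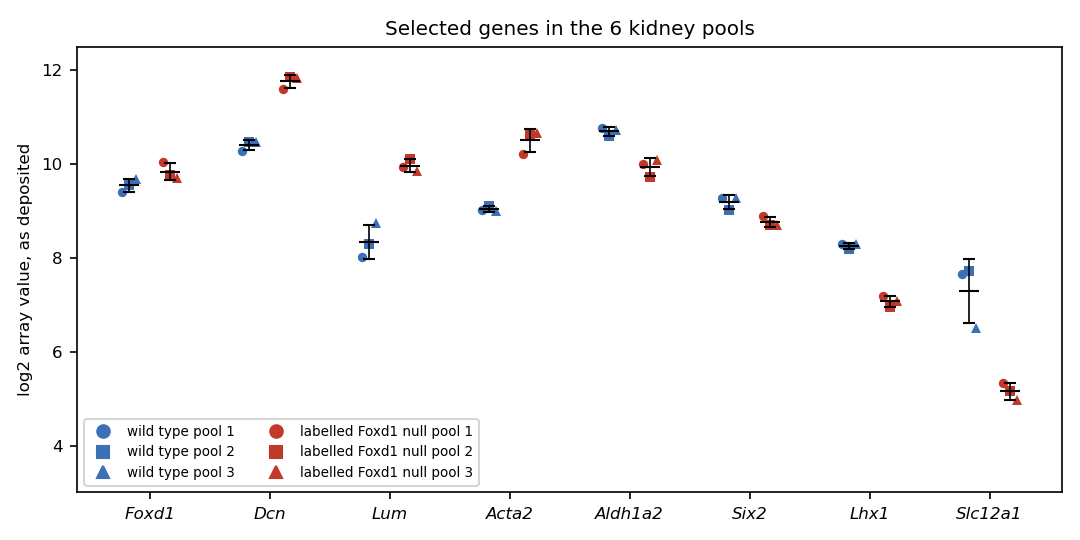
Deposited log2 array values of 8 genes in each pool; blue points are wild type pools, red points pools labelled Foxd1 null, marker shape is the pool number, and black bars are mean and SD of 3 pools. Dcn lies near 11.77 in the pools labelled null and near 10.41 in wild type, while Foxd1 lies at 9.84 and 9.55.

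**Figure D2:**
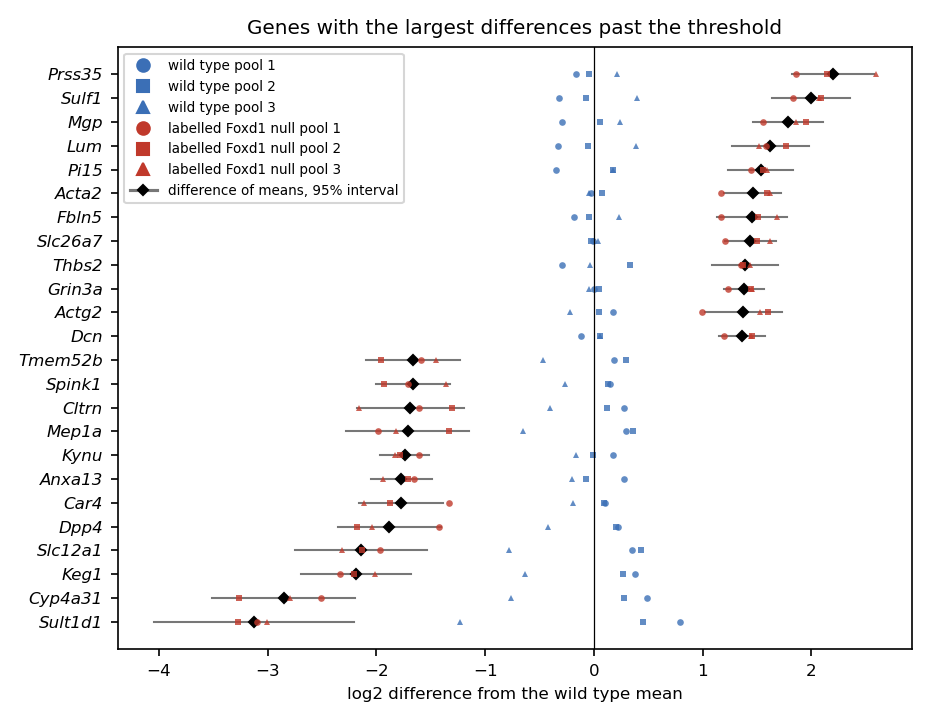
Log2 differences from the wild type mean for the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold; diamonds and grey lines are the difference of group means with its 95% interval, colored points are single pools. Sult1d1 fell by 3.13 on the log2 scale and Prss35 rose by 2.20.

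Of the 23 measured genes of the list of fibrillar collagens and other fibroblast matrix, 14 rose, 0 fell and 9 did not pass; 21 rose when adjusted over the list alone. Its median log2 difference was 0.53, and the list ranked above other genes (camera adjusted p = 3e-23; adjusted p = 0.104 with an estimated correlation). Thbs2, a matricellular protein, rose by 1.39 (SE 0.14), the fibril-associated collagens Col12a1 and Col14a1 rose by 1.05 (SE 0.09) and 1.00 (SE 0.10), and elastin (Eln) rose by 1.03 (SE 0.20, adjusted p = 0.0268). The number of members past the threshold was 16 without null-labelled pool 1, 5 without pool 2, 8 without pool 3, and 7, 7 and 11 without wild type pools 1, 2 and 3. Eln passed only without null-labelled pool 1 (adjusted p up to 0.123 when 1 other pool was left out). Among 14 small leucine-rich proteoglycans 4 rose (Lum by 1.62, SE 0.16; Dcn; Bgn by 0.78, SE 0.11; Ogn by 0.70, SE 0.11), 0 fell and 10 did not pass, or 7 rose when adjusted over the list alone. That list ranked above other genes (camera adjusted p = 2.9e-07; adjusted p = 0.0891 with an estimated correlation), but it was made knowing the study's interest in decorin and is no independent evidence of direction. Ogn did not pass without null-labelled pool 2 or wild type pool 1 (adjusted p up to 0.0619). Beside these genes, marker lists of other tissues stood higher in some pools labelled null, with medians given below for each pool.

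Of 14 genes of medullary and ureteric stroma and smooth muscle, 6 rose, 0 fell and 8 did not pass, and 6 rose when adjusted over the list alone (camera adjusted p = 1.4e-06; adjusted p = 0.0891 with an estimated correlation). Smooth muscle actin Acta2 rose by 1.46 (SE 0.12) and enteric actin Actg2 by 1.37 (SE 0.16), while Tagln rose by 1.08 (SE 0.16) and Cnn1 by 0.92 (SE 0.15), both regulators of smooth muscle contraction. The count was 3 without wild type pool 2 or 3, where Cnn1 lost its call (adjusted p up to 0.0607). Of 13 genes of the renal capsule and the mesenchyme around the kidney, 4 rose (Tbx18 by 0.89, Osr1 by 0.84, Gata6 by 0.69 and Foxf1 by 0.48), 1 fell (Wt1, named after its value was seen) and 8 did not pass. This list ranked above other genes (camera adjusted p = 5e-04; adjusted p = 0.104 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone). Foxf1 lost the call when null-labelled pool 2 or any wild type pool was left out (adjusted p up to 0.0766), and Wt1 lost its call in 5 of 6 leave-one-out fits, where 0 members of the list fell. The skeletal muscle and neuron lists, given below, also stood higher in some pools labelled null.

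Of 25 endothelial genes 6 rose, 0 fell and 19 did not pass (13 rose adjusted over the list alone; camera adjusted p = 1.2e-10; adjusted p = 0.285 with an estimated correlation). Examples were Clec14a with 0.65 (SE 0.10) and Pecam1, a junction protein of endothelium, with 0.54 (SE 0.10). Of 16 genes of pericytes and mural cells 3 rose (Rgs5 by 1.21, Angpt2 by 0.92 and Olfml2b by 0.88), 0 fell and 13 did not pass (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.1e-05; adjusted p = 0.373 with an estimated correlation). Of 8 genes of renin cells and mesangium 2 rose (Sfrp2 by 0.76 and Pdgfra by 0.44), with camera adjusted p = 0.0011 and adjusted p = 0.185 with an estimated correlation, and 2 rose adjusted over the list alone. Of these 8 genes 3 also stand in another list, among them Sfrp2, which is counted again in the pretubular list below. Ren1 itself was not among the genes tested. Of 19 macrophage genes 4 rose (Mrc1 by 0.65, SE 0.10; Tyrobp by 0.59, SE 0.09; Ctss by 0.69; Ptprc by 0.42), 0 fell and 15 did not pass. All 19 lay above 0, 11 rose when adjusted over the list alone, and camera gave adjusted p = 6.8e-10 (adjusted p = 0.287 with an estimated correlation). The endothelial count was 10 without null-labelled pool 1, 1 without pool 2 or wild type pool 1 or 2, and 2 without null-labelled pool 3 or wild type pool 3. The macrophage count was 9 without null-labelled pool 1, 1 without pool 2 or wild type pool 1, and 2 without wild type pool 2 or 3. The mural count was 6 without null-labelled pool 1, and the median of that list, 0.28, was 0.18 without pool 2 or 3. Rgs5, Angpt2, Sfrp2 and Mrc1 kept their calls in all leave-one-out fits; Clec14a and Tyrobp lost theirs in 2 of 6, Olfml2b and Ctss in 4, and Pecam1, Pdgfra and Ptprc in 5 (adjusted p up to 0.171, for Pdgfra). The neuron and muscle lists below also stood higher in some of these pools, nerve markers in pools 2 and 3.

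Of 22 measured genes of the pretubular aggregate and renal vesicle, 8 fell, 2 rose and 12 did not pass (12 lower and 2 higher adjusted over the list alone), and the list kept its call with an estimated correlation (camera adjusted p = 4.4e-09; adjusted p = 0.0492 with an estimated correlation). Lhx1, Osr2 (fell by 1.01, SE 0.09), Cdh6 (fell by 0.85, SE 0.09) and Pax8 (fell by 0.77, SE 0.11) fell in every leave-one-out fit, while the 2 that rose, Bmper and Sfrp2, are secreted modulators of BMP and Wnt signals (Bmper named after its value was seen). Without wild type pool 1 or 2, 4 members of this list fell. Of 15 genes of the loop of Henle and distal tubule, 5 fell, 0 rose and 10 did not pass, 7 lower adjusted over the list alone, with camera adjusted p = 3e-09 and adjusted p = 0.0492 with an estimated correlation. Among them the sodium-potassium-chloride cotransporter Slc12a1 fell by 2.14 (SE 0.27), Tmem52b by 1.67 (SE 0.19), Sostdc1 by 1.15 (SE 0.12) and Sim1 by 0.74 (SE 0.10). Of 18 proximal tubule genes 7 fell, 0 rose and 11 did not pass (11 lower adjusted over the list alone; camera adjusted p = 1.2e-10; adjusted p = 0.203 with an estimated correlation). Lrp2, the megalin receptor, fell by 1.59 (SE 0.20), Keg1 by 2.19 (SE 0.23), Pdzk1 by 0.94 (SE 0.14) and Cubn by 0.93 (SE 0.19). Wild type pool 3 stood apart on these genes, with a list median of -0.19 against 0.11 in both other wild type pools, and Slc12a1 was 6.51 in it against 7.65 and 7.73. Cubn, however, did not pass in 5 of the 6 leave-one-out fits (adjusted p up to 0.16), and 4 members of the list fell without wild type pool 1. Of 15 podocyte genes 1 fell, Clic5 by 0.49 (SE 0.09), and 14 did not pass (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0027; adjusted p = 0.304 with an estimated correlation). Clic5 lost its call in 4 of 6 leave-one-out fits (adjusted p up to 0.107), so that 0 podocyte genes fell there, while 3 fell without wild type pool 3 and 2 without null-labelled pool 1. The list lost its call with the filter on low rows (0.0588).

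Of 20 nephron progenitor genes 1 rose (Osr1) and 1 fell (Cited1, by 0.53, SE 0.11, adjusted p = 0.046), with a list median of -0.05 and no call (camera adjusted p = 0.225; 3 higher and 3 lower adjusted over the list alone). Cited1 did not pass in 5 of the 6 leave-one-out fits (adjusted p up to 0.187), and the list was called lower without null-labelled pool 1 (adjusted p = 0.0374). Of 15 cortical stroma genes 1 rose (Ntrk3, by 0.78, SE 0.11) and 2 fell (Aldh1a2, and Ntn1 by 0.36, SE 0.08), again with no call (camera adjusted p = 0.485; 5 higher and 4 lower adjusted over the list alone). Ntn1 did not pass in any of the 6 leave-one-out fits (adjusted p up to 0.187), and Ntrk3 did not pass without null-labelled pool 2 (adjusted p = 0.0505). Without null-labelled pool 1, 3 cortical stroma genes rose and 3 fell. Without pool 2, 0 rose and 1 fell, and without any other pool 1 rose and 1 fell. No gene of the ureteric bud tip passed among 15 (camera adjusted p = 0.875; 1 higher and 1 lower adjusted over the list alone), and the level of Etv5 there differed by -0.34 (adjusted p = 0.101; 0.0251 without null-labelled pool 1 and 0.0493 with the filter on low rows, up to 0.322 over its alternatives). Of 23 genes of ureteric trunk, collecting duct and urothelium 3 rose (Upk1b by 0.89, SE 0.09; Krt19 by 0.53; Gata2 by 0.37) and 1 fell (Emx2, by 0.62), with no call (camera adjusted p = 0.582; 4 higher and 1 lower adjusted over the list alone). Only Upk1b of these 4 kept its call in all leave-one-out fits, with adjusted p up to 0.207 for Gata2.

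Of 22 BMP and TGF-beta ligands and receptors 2 rose (Bmp5 by 0.89, SE 0.10, and Tgfb3 by 0.60) and 1 fell (Bmp2, by 0.98, SE 0.11), with 6 higher and 2 lower adjusted over the list alone. The list ranked above other genes (camera adjusted p = 0.0184; adjusted p = 0.303 with an estimated correlation). Tgfb3 lost its call in 3 of 6 leave-one-out fits (adjusted p up to 0.0722). Of 17 readouts of this signalling 0 passed (camera adjusted p = 0.907), where Id2 differed by 0.16 and Tgfbi by -0.15, and 1 was lower adjusted over the list alone. Of 15 canonical Wnt targets 1 fell (Dkk1 by 0.57, which lost the call in 4 of 6 leave-one-out fits, adjusted p up to 0.143); the list median was 0.02 but its mean -0.07, with camera pointing lower at adjusted p = 0.241 (0.0335 without null-labelled pool 2 and 0.0463 with the filter on low rows). Of 16 retinoic acid pathway genes Aldh1a2 fell and Aldh1a3 rose by 0.37, the latter not in 5 of 6 leave-one-out fits (adjusted p up to 0.129), and camera gave adjusted p = 0.754. Of 13 Hippo pathway targets 0 passed (camera adjusted p = 0.121; 1 higher adjusted over the list alone). Among them Tgfb2 differed by 0.54 (adjusted p = 0.151), and it passed with the replicate block (0.0361) and without wild type pool 3 (0.00963), with up to 0.432 over its alternatives.

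All 23 measured cell cycle genes had log2 differences below 0 (median -0.20), but 0 passed over all genes and 7 were lower adjusted over the list alone. As a set they ranked below other genes (camera adjusted p = 3.9e-10; adjusted p = 0.246 with an estimated correlation); Top2a differed by -0.09 and Pcna by -0.17. The 23 oxidative phosphorylation genes had a median of -0.08 (0 passed; camera adjusted p = 0.000132; adjusted p = 0.299 with an estimated correlation), and the 30 Hox genes one of -0.05 (0 passed; camera adjusted p = 0.0472; adjusted p = 0.751 with an estimated correlation). The Hox call was lost without null-labelled pool 2 or 3 or wild type pool 3 (adjusted p up to 0.514), and also with the replicate block (0.0541), the filter on low rows (0.0588), median centring (0.0506) and array weights (0.0706). Of 18 hypoxia genes P4ha1 rose by 0.56, a call lost in 5 of 6 leave-one-out fits with adjusted p up to 0.145 (camera adjusted p = 0.0435; adjusted p = 0.451 with an estimated correlation); the list lost its call without null-labelled pool 1 or wild type pool 2 (adjusted p 0.23 and 0.124) and with the filter on low rows (0.0991). Camera gave no call for ribosomal proteins (adjusted p = 0.425), heat shock (0.969), p53 targets (0.804, where Plk2 rose by 0.72, SE 0.07), immediate early genes (0.482), red blood cells (0.251), cartilage and bone (0.482), gonad and ducts (0.425) and Y-linked genes (0.969). Red blood cell genes were called higher without null-labelled pool 2 (adjusted p = 0.00989) or wild type pool 3 (adjusted p = 0.0321).

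Markers of tissues next to the kidney differed between pools of the same label. The 18 neuron and glia genes had medians of 0.03, 0.89 and 0.74 in null-labelled pools 1, 2 and 3 against -0.22 to 0.16 in wild type, and the list ranked above other genes (camera adjusted p = 2.3e-07; adjusted p = 0.373 with an estimated correlation). Elavl4 was the only member that passed (0.62, adjusted p = 0.0383), and 11 were higher adjusted over the list alone; without null-labelled pool 1, 11 passed, and without any other pool 0. The 23 skeletal muscle genes had medians of 1.01, 0.65 and 0.16 in null-labelled pools 1, 2 and 3 against -0.35 to 0.30 in wild type (camera adjusted p = 1.4e-05; adjusted p = 0.373 with an estimated correlation), with Tnnt3 past the threshold (1.09, adjusted p = 0.0401); 4 members passed without null-labelled pool 3 and 0 without any other pool. Liver and gut genes had a median of 1.60 in null-labelled pool 3 against -0.04 and -0.20 in pools 1 and 2, and adrenal cortex genes 1.02 against -0.24 and -0.22. Alb stood at 10.64 in null-labelled pool 3 and between 5.81 and 7.45 in the other 5 pools, and Star at 9.56 against 6.53 to 7.39. Neither list was called (camera adjusted p = 0.268 for liver and gut and 0.462 for adrenal cortex). Without null-labelled pool 3 both were called lower (adjusted p 0.0168 and 0.00306). Liver and gut was called higher without pool 2 (adjusted p = 0.00989) and adrenal cortex without pool 1 (adjusted p = 0.0468). Vil1, the 1 liver and gut gene past the threshold, fell by 0.59, a call lost in 4 of 6 leave-one-out fits (adjusted p up to 0.123).

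**Figure D3:**
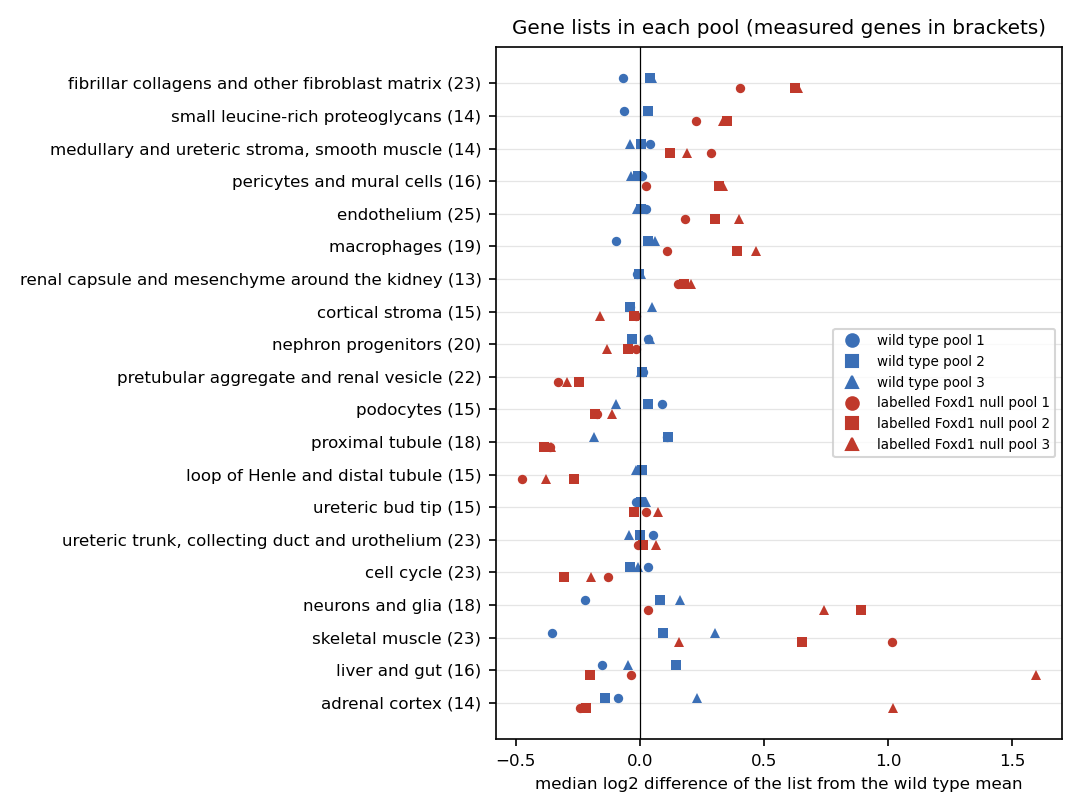
Median log2 difference from the wild type mean of 20 gene lists in each pool, the number of measured genes in brackets; blue is wild type, red is labelled Foxd1 null, and marker shape is the pool number. The fibroblast matrix medians of the null-labelled pools lie at 0.40, 0.62 and 0.64, while liver and gut stands at 1.60 in pool 3 only.

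The authors' deposited table lists 488 probe sets, of which 237 have a p under 0.05 in it, 113 higher and 124 lower in null. Dcn has a fold of 2.49 and a p of 0.0002 in the authors' deposited table, Aldh1a2 a fold of -1.85 with p 0.000508, and Lhx1 -2.21 with p 0.00216. Of the 12 largest falls 10 are listed there, and 9 of these are smaller in that table than in the limma fit: Sult1d1 has a fold of -3.72 where the fit gives 8.75-fold lower, Cyp4a31 -3.02 against 7.23-fold, Keg1 -3.17 against 4.56-fold and Cltrn -1.97 against 3.23-fold. All of these falls but that of Dpp4 end near background, as given above, so neither set of folds gives their exact size. Of the 12 largest rises 10 are listed, and 7 of these are smaller in the table, Thbs2 with 2.04 against 2.61-fold. Of the 440 listed probe sets tested here as genes, 215 had a p under 0.05 in the authors' deposited table; 207 of them had the same direction in the limma fit and 134 passed its threshold. The table is a selection, so these shares do not extend to all genes.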

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

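The rows that carry no single gene symbol take no part in the comparison of genes. In a fit over all 35556 rows, 8 of these 13767 rows were higher and 7 were lower in the pools labelled Foxd1 null past an adjusted p of 0.05. The rises ran from 0.54 to 1.29 and the falls from -0.57 to -2.04 in log2 units. At an unadjusted p under 0.05 there were 1367 rows, and limma called 0 when these rows were tested alone. Without a gene name these rows are not interpreted here.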

How the results depend on the processing

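All 479 calls kept their direction in each alternative in which they were tested, and how many stayed past the threshold varied. The groups did not overlap in any of the 479, so leaving out 1 pool could not turn a direction. Several other fits used the same differences of means, so the kept directions are no support of their own. The Foxd1 difference was 0.19 to 0.37 when 1 pool was left out (adjusted p 0.223 to 0.585) and stayed short of the threshold in all alternatives. Leaving out 1 pool gave 127 to 572 genes higher, 64 to 171 lower and 18 to 21 lists. Requiring 1.5-fold gave 164 and 90. Testing all rows of the table gave 71 rows higher and 37 lower, with 2.85 prior degrees of freedom against 5.65. With an intensity trend, chosen after seeing the data, the same test gave 105 and 54 rows. A plain two-sample test gave 1 and 1. Camera with an estimated correlation called 2 lists and fry 7, where the preset called 19. The plain test leaves out the variance model of eBayes, and why the counts changed was not tested.

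Quantile normalization gave 267 higher and 174 lower and median centring 295 and 185. The Xist covariate, also added later, gave 329 and 154 and kept 428 of the 479. The replicate block gave 381 and 158 genes and kept 416 of the 479. Same-numbered pools had correlations of deviations of 0.125, 0.068 and 0.053. These were not set against those of differently numbered pools, so whether the numbers pair the pools is not settled. Without null-labelled pool 3 the adrenal cortex list turned to -0.20 and the liver and gut list to -0.12 (up to 0.37 and 0.78 without 1 other pool). Of the values of named genes under alternatives, 1304 kept their side of the threshold, 134 lost it and 13 gained it; of those of lists, 579, 40 and 7, with 2 reversed. With 6 arrays and a median SE of 0.086, small differences stay below detection.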

Other observations

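The tests of explanations below were all chosen after the results were seen, and so were the demand for 2 pools in the tests of carried-over tissue and the second conditions of the tests on ureteric genes and small-RNA rows. An earlier form of that test judged by 1 pool and would have excluded muscle and nerve too.

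Of 48 measured genes of the imprinted Dlk1-Dio3 region, picked out after the values were seen, 11 rose, 0 fell and 37 did not pass (camera p = 4.4e-16 with the preset; p = 0.0645 with an estimated correlation). The long non-coding RNA Rian rose by 1.24 (SE 0.15, adjusted p = 0.00323), while Meg3 differed by 0.76 (adjusted p = 0.0725) and Dlk1 by 0.56 (adjusted p = 0.0884). The other 10 that rose were microRNA rows at or below percentile 15.1 of mean levels, not shown to be above background, so their sizes are not given. Xist, made from the inactive X chromosome, was low in null-labelled pool 1 and wild type pool 3 (5.65 and 6.02) and high in the other 4. With Xist as a covariate 329 genes were higher and 154 lower, and 428 of the 479 calls stayed past the threshold.

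The gene counts were set against the other 9 of the 10 splits of the 6 arrays. For genes higher, genes lower and lists 1 split, the real one, gave a count as large in each case. The real split gave 326, 153 and 19, and the highest of the others 0, 0 and 15. Each of the other 9 splits called 4 to 15 lists although it called 0 genes. Camera at its preset thus also calls lists in groupings that mix the labels, and such a call is not by itself evidence of a genotype difference. With 10 splits the share is never under 0.1.

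The Foxd1 row was not lower in the pools labelled null. An exchange of 1 null and 1 wild type label is argued against by the 9 splits that exchange 1 pool of each, which call 0 genes where the labels call 479. An exchange of all labels between the groups gives the same split with every direction reversed. These splits cannot see it, so it stays open. Scaling between arrays is argued against by lower 95% bounds of 0.014 under median centring and 0.047 under quantile normalization. A row that still measures RNA of the null allele stays open: it lies at percentile 91.8 of all genes in these pools, which cross-hybridisation could give as well, and probe positions were not used.

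Matrix and proteoglycan genes were higher in all 3 pools labelled null, with medians of 0.36, 0.57 and 0.58 against at most 0.05 in wild type. Carried-over liver or adrenal tissue is argued against by null-labelled pools 1 and 2, whose liver and adrenal medians were not above wild type and whose lowest matrix median was 0.36. Skeletal muscle and nerve stay open, since only 1 pool each had no excess of them over the wild type range, pool 3 with a matrix median of 0.58 and pool 1 with 0.36; 14 of the 23 muscle and 9 of the 18 nerve genes lie above the median gene in wild type, Actc1 reaches 11.46 and Fabp7 11.16. A smaller share of nephron epithelium that raises all other types alike is argued against by a difference of 0.48 from the ureteric genes, which was at least 0.34 in each null-labelled pool and at most 0.06 in wild type. This speaks only against that strict form, as the ureteric genes are epithelial too. The endothelial, macrophage and mural lists had medians of 0.27, 0.29 and 0.28, and the cortical stroma list -0.09. A smaller share of epithelium in general therefore stays open. More connective tissue around the kidney may contribute and cannot be told apart, as the capsule list had a median of 0.18 too (camera adjusted p = 5e-04; adjusted p = 0.104 with an estimated correlation), and a change in the stroma with genotype was not separated from it.

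For the Dlk1-Dio3 region, the median of small-RNA rows was 0.24 above that of small-RNA rows elsewhere (0.28 against 0.04). The region was chosen for its high values and its rows are correlated, so this gap alone does not decide. Of the 309 small-RNA rows outside, 3 rose and 1 fell past the threshold, against 10 of 40 that rose in the region. A general rise as large as in the region was therefore not seen outside it. A weaker general rise stays open, as 200 of the 309 lay above 0. Nerve and muscle tissue stay open, with region medians of 0.17 in the pool without a nerve excess and 0.31 in the pool without a muscle excess, against 0.11 at most in wild type. A rise of the region as a whole stays open, with a camera p of 0.0645 once the correlation was estimated (4.4e-16 with the preset).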
